A study of Homo sapiens and Mus musculus with 18 samples.

How the data were processed

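Transcripts were measured by RNA sequencing in 2 lymphoma cell lines, the human Burkitt lymphoma line BL41 and the mouse line J3D, to which the labels give the same tumour type. Each line had 3 groups of 3 libraries, 18 samples in all. The groups were sham-handled cells, cells given 5 Gy of X-rays from a 6 MV linear accelerator and cells given 5 Gy of protons. Per the labels' protocols, the proton beam was scanned over cells held in the middle of the spread-out Bragg peak, with energies from 129.3 to 148.2 MeV/u and a median linear energy transfer of 3.5 keV/µm (2.9 to 7.9 keV/µm). Cells had been resuspended 6 h before exposure, sham cells stood at room temperature meanwhile, and total RNA was taken 12 h after irradiation. Libraries followed Illumina protocols per the labels, and whether they kept the strand is not given in the sources used here. The labels do not say that replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

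TopHat2 and the builds hg19 and mm10 are named in the submitters' processing notes, and the counting tool, the annotation and the normalization are not given in the sources used here. The authors deposited 1 table per line, with 15069 genes for BL41 and 12264 for J3D. The values the authors deposited are logarithms relative to a baseline, and they were read as log2 because no source names the base. Another base would multiply every fold change by the same factor and leave the tests as they are.

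The values themselves showed how the baseline was set. Within each replicate number a gene's values were centred on the mean of 4 libraries, of which 3 were analysed here. Where a pair of the 3 values was tied at the lowest value (within 1e-06), the library not analysed here was implied to lie exactly at that value for 52.9 to 63.5% of those genes, and below it for 0 genes. The tables therefore hold no absolute expression level, and the sequencing depth is unknown. The precision of each value is given by the spread between libraries alone. Since the mean of each replicate number had been removed, the correlation of same-numbered libraries (−0.823 to 0.61) was biased by the centring and could not show whether the numbers pair the samples, and the labels do not say what the numbers mark. Both ends of that range came from J3D number 1. There r was 0.61 between sham and X-ray, −0.814 between sham and proton and −0.823 between X-ray and proton.

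Fold changes and tests were computed with limma 3.58.1 in R 4.3.3, with statmod 1.5.0 for robust variance moderation. Tables and plots used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Each line was fitted separately on its 9 libraries with a mean per group, a trend in the prior variance and robust moderation, and the Benjamini-Hochberg adjusted p threshold was 0.05. Values were used as deposited, without a pseudocount. The planned filter, a value above the lowest of the table in at least 3 libraries, removed 0 genes. Rose, fell, higher and lower are used of genes past the limma threshold, or past it with p adjusted over the list alone where the text says so. Of the BL41 genes, 655 have a symbol that stands on more than 1 line of the table, and each line was tested by itself.

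The number in the sample titles was not a term of the model, as fixed before the data were examined. Because the authors' centring had removed a mean per number, this model counts more residual degrees of freedom (6) than the fit with the number as a block (4). Both were tested on simulated data with 200 changed genes and 10 draws, built on the BL41 comparison of X-rays with sham (15069 genes). The model without the block recovered 30.4, 83.0, 94.0 and 98.6% of genes changed by 0.5, 1, 1.5 and 2 on the log2 scale, 15.3% of its calls were false, and 8.62% of unchanged genes had an unadjusted p under 0.05. With the block these values were 7.8, 52.2, 83.6 and 92.2%, 6.13% and 4.83%. On the J3D comparison of X-rays with sham (12264 genes) the model without the block recovered 24.8, 86.8, 96.0 and 97.8%, with 16.9% false calls and 8.78% of unchanged genes under 0.05. With the block the J3D values were 7.0, 58.6, 87.6 and 95.8%, 5.82% and 4.92%. The model without the block is thus too liberal, and the blocked count stands beside the number of genes called in each contrast.

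The 20 fixed gene lists covered p53 targets, mitosis and G2/M, G1/S and DNA replication, clustered histones, DNA repair and damage signalling, apoptosis regulators, interferon-stimulated genes, NF-kB targets, MYC and ribosome biogenesis, the integrated stress and unfolded protein responses, sterol synthesis, oxidative phosphorylation, glycolysis and hypoxia, NRF2 and antioxidant genes, B-cell and germinal-centre genes, plasma-cell differentiation, antigen presentation, T-cell and NK-cell markers, myeloid markers, and stromal, epithelial and erythroid markers. Each list was compared with all other genes by limma's camera with a preset correlation of 0.01, adjusted over the 20 lists of a contrast. Camera with a correlation estimated from the residuals and fry were alternatives. Members were also counted with p adjusted over the list alone. Mouse and human genes were matched by symbol, ignoring case.

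Genes were named by a rule fixed with the lists. Among genes with an official-looking symbol, without pseudogenes, clone names and the like, it took the 8 highest and 8 lowest fold changes among genes past the threshold with every irradiated library on the same side of every sham library, up to 3 members of each list past the threshold (or, with none past it, the 2 with the smallest p, as values), and a fixed set with CDKN1A, MDM2, MYC, BBC3 and PMAIP1 and their mouse counterparts. For protons against X-rays it took the 4 genes with such a symbol that had the smallest p. The rule's criterion on mean level could not be applied to centred values, and some values of lists with no member past the threshold are left out for space. Some genes that the rule names are not reported here.

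The X-ray and proton responses share the same 3 sham libraries, so their correlation and covariance across genes were set beside 50 simulated draws of unchanged groups against shared controls (20 draws for counts of calls). The draws were repeated with the 3 libraries of number 2 (BL41) or 1 (J3D), or X-ray library 2, left out. All draws took the noise of each gene as independent of other genes, so their range may be too narrow. They also gave every library of a gene the same noise, estimated from all 9 libraries of the line. Alternatives were libraries rescaled by trimmed means (a fraction of 0.3 trimmed from each side, in place of the planned TMM factors), quantile normalization, the replicate block, moderation without trend and robust, the 6 libraries of the compared groups alone, an absolute log2 fold change of at least 1, and leaving out each library in turn. Alternatives added after seeing the data were the block together with other settings, omission of the 3 libraries of number 2 (BL41) or 1 (J3D), and genes without ties at the lowest value. For the correlation of the X-ray and proton responses, leaving out each library was also added then. So was the overlap between the lines at an unadjusted p under 0.05. Another pseudocount, the unfiltered and stricter-filtered settings and DESeq2 were not run, because the values are centred logarithms. The authors' columns of group means and the genome coordinates were not used here.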

Results

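RNA of the human line BL41 and the mouse line J3D was profiled 12 h after sham handling, 5 Gy of X-rays or 5 Gy of protons, with 3 libraries per group and line. The values are centred log2 expression values of 15069 genes in BL41 and 12264 in J3D, without absolute levels, and the depth of the libraries is unknown. All fold changes are on the log2 scale, and ± gives the standard error where it is shown. In BL41, sham library 2 had the lowest mean of all genes (−0.133). In J3D the 3 libraries of number 1 had interquartile ranges of 0.342 (sham), 0.395 (X-ray) and 0.371 (proton), while the other 6 lay between 0.140 and 0.238.

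The first comparison asked which transcripts differed in BL41 after X-rays. CDKN1A, which encodes the cell-cycle inhibitor p21, rose by 0.84 ± 0.09 (n = 3 libraries per group, limma adjusted p = 0.00869). Among the highest fold changes were GNG8, a G protein gamma subunit (2.34 ± 0.30, limma adjusted p = 0.0122), the cytokine IL32 (2.32 ± 0.29, 0.011), EBI3, a subunit of interleukin 27 (1.68 ± 0.33), and the lysosomal sialidase NEU1 (1.51 ± 0.27). The chemokine genes CCL17, CCL5 and CCL3 rose by 1.64 ± 0.34, 1.45 ± 0.12 and 1.41 ± 0.33, and HMOX1, which encodes the haem-degrading enzyme haem oxygenase, by 1.33 ± 0.16 (limma adjusted p = 0.011). Among the deepest falls were those of the aminoacylase gene ACY3 (−1.26 ± 0.23, limma adjusted p = 0.0239), the cell-adhesion gene CNTN5 (−1.09 ± 0.17), FAM163B (−1.05 ± 0.25), LSM14A, which encodes a processing-body protein (−1.03 ± 0.12), the taste-receptor gene TAS1R3 (−1.01 ± 0.19), the potassium-channel gene KCNN3 (−0.97 ± 0.23) and the kinase gene WNK2 (−0.96 ± 0.14).

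Some genes of DNA replication and histone supply fell after X-rays. Of 36 G1/S and DNA replication genes, 10 fell and 0 rose (21 fell adjusted over the list alone). They included SLBP, which encodes the protein that binds histone mRNA (−0.62 ± 0.07, limma adjusted p = 0.00831), the replication clamp PCNA (−0.54 ± 0.07) and the ribonucleotide reductase subunit RRM2 (−0.54 ± 0.10). Of 26 clustered histone genes, 4 fell and 0 rose (10 and 1 adjusted over the list alone), with HIST1H2BK at −0.94 ± 0.17, HIST1H3D at −0.64 ± 0.14 and HIST1H2BD at −0.61 ± 0.14; near-identical copies make single histone genes uncertain. Both lists lay below other genes (camera adjusted p = 3.62e-25 and 2.12e-13, and adjusted p = 0.0258 for each with an estimated correlation). Rescaled by trimmed means and with an estimated correlation, the G1/S list kept its call (camera adjusted p = 0.0106) and the histone list lost it (0.0631). Of 35 mitosis and G2/M genes, the spindle kinase gene AURKB rose (0.48 ± 0.08) and 34 did not pass, and the list did not pass (camera adjusted p = 0.102, but 0.0437 with the replicate block, lost at adjusted p = 0.702 with the block and an estimated correlation). Of 30 MYC and ribosome biogenesis genes 0 passed, MYC itself being at −0.36 ± 0.11 (limma adjusted p = 0.0874) and NPM1 at −0.21. That list lay below other genes (camera adjusted p = 6.33e-05), a call lost at adjusted p = 0.649 with an estimated correlation. Relative to all genes it was at −0.239, 0.0295 and −0.265 in numbers 1 to 3.

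Single members of the immune lists rose after X-rays. Of 23 NF-kB targets, 5 rose and 0 fell (7 and 0 adjusted over the list alone), among them CCL3, EBI3 and the chemokine gene CCL22 (1.05 ± 0.19). The list as a whole did not pass (camera adjusted p = 0.0643). It passed with the replicate block (camera adjusted p = 0.0437, lost at adjusted p = 0.702 with the block and an estimated correlation), with trimmed means (0.0259, lost at 0.563 with an estimated correlation) and with quantile normalization (0.0305, lost at 0.564). Of 29 interferon-stimulated genes, 4 rose and 0 fell (9 and 0 adjusted over the list alone), with OASL at 0.51 ± 0.12 and the transcription factors STAT2 and IRF7 at 0.46 ± 0.11 and 0.39 ± 0.09. Of 26 antigen presentation genes, 3 rose and 0 fell (6 and 0 adjusted over the list alone). These 3 were HLA-DQA1 (0.74 ± 0.15), HLA-DRB1 (0.67 ± 0.14) and HLA-DQB1 (0.63 ± 0.14), class II genes whose reads are shared with other haplotype copies and whose values are uncertain. The interferon and antigen presentation lists lay above other genes (camera adjusted p = 0.0156 for each), calls lost at adjusted p = 0.273 and adjusted p = 0.358 with an estimated correlation. With trimmed means or quantile normalization 0 members of either list rose and 3 NF-kB targets did. Of 34 B-cell and germinal-centre genes 2 rose, the homing receptor CCR7 (0.83 ± 0.15) and CD72 (0.41 ± 0.09). None fell (camera adjusted p = 0.102). Of 10 plasma-cell genes TNFRSF13B rose (0.52 ± 0.10) and IGJ, which encodes the antibody joining chain, fell (−0.58 ± 0.11; camera adjusted p = 0.102).

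With the values as deposited, the stress and metabolic lists did not pass as groups after X-rays. Of 30 p53 targets, CDKN1A and the death receptor FAS (0.55 ± 0.13) rose and 0 fell (camera adjusted p = 0.504), while MDM2 was at −0.30 ± 0.16 (limma adjusted p = 0.303), BBC3 at −0.14 and PMAIP1 at −0.10. Of 28 apoptosis regulators, FAS and BAD (0.41 ± 0.09) rose (camera adjusted p = 0.9). CHEK2, the checkpoint kinase, rose by 0.36 ± 0.09 among 39 DNA repair genes (camera adjusted p = 0.336; 0 adjusted over the list alone). HMOX1 and the pentose phosphate enzyme PGD (0.32 ± 0.07) were among the 3 risers of 20 NRF2 and antioxidant genes (camera adjusted p = 0.202). The glucose transporter SLC2A3 (0.73 ± 0.12) and the enolase ENO2 (0.52 ± 0.12) rose among 30 glycolysis genes (camera adjusted p = 0.202), and 2 of 38 oxidative phosphorylation genes rose, among them SDHC at 0.35 ± 0.06 (camera adjusted p = 0.0643). The oxidative phosphorylation list lay below other genes with trimmed means (camera adjusted p = 0.0145, lost at adjusted p = 0.8 with an estimated correlation) and quantile normalization (0.0155, lost at 0.84). No member passed among 25 stress-response genes (ATF3 at 0.53, SLC7A11 at 0.32; camera adjusted p = 0.433) or 23 sterol synthesis genes (DHCR7 at 0.28, MVD at 0.26; camera adjusted p = 0.504). Of the markers of other cell types, CD163, the 1 myeloid marker in the table, rose (0.64 ± 0.15; camera adjusted p = 0.185). None of 5 T-cell and NK-cell markers (camera adjusted p = 0.687) or 4 stromal, epithelial and erythroid markers (camera adjusted p = 0.9) passed.

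In total 728 genes were higher and 78 lower after X-rays (limma, 806 of 15069; 3555 at an unadjusted p under 0.05; 90.3% of calls higher). With the replicate number as a block limma called 0 genes (lowest adjusted p = 0.0718, 2428 at an unadjusted p under 0.05). All 806 had an unadjusted blocked p under 0.05 and the same sign in all 3 numbers. Since they were picked from the same libraries, this is no separate support for the calls. With the block and p adjusted over the list alone, 13 G1/S and 8 histone genes fell, and 8 interferon-stimulated, 4 NF-kB and 2 antigen presentation genes rose. The 44 named genes past the threshold had blocked adjusted p between 0.0718 and 0.186 in limma. The median fold change of all genes was 0.09, and with libraries rescaled by trimmed means 217 genes were higher and 117 lower (65% higher), or 74 and 55 with quantile normalization (57.4% higher). The count was 0 without X-ray library 1, 48 without sham 3, 143 without X-ray 2, 233 without sham 2, 246 without X-ray 3, 325, 314 and 322 without proton libraries 1, 2 and 3, and 808 without sham 1.

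The second comparison asked the same of protons in BL41. CDKN1A rose by 0.78 ± 0.09 (n = 3 libraries per group, limma adjusted p = 0.0129) and HMOX1 by 1.34 ± 0.16 (0.0129). The highest fold changes were those of GNG8 (2.46 ± 0.30, limma adjusted p = 0.0129), CCL17 (2.29 ± 0.34, 0.0167), IL32 (2.14 ± 0.29, 0.0153), EBI3 (1.91 ± 0.33) and CCL3 (1.87 ± 0.33). The chemokine genes CCL4L2 (1.84 ± 0.35), CCL3L1 (1.57 ± 0.19) and CCL4 (1.53 ± 0.37) also rose, but they have near-identical copies and their values, with that of CCL3, are uncertain. Among the deepest falls were those of ACY3 (−1.54 ± 0.23, limma adjusted p = 0.0167), the secreted factor gene FAM3B (−1.49 ± 0.26), the lipogenesis regulator THRSP (−1.42 ± 0.27), the T-box gene TBX10 (−1.34 ± 0.24), SUSD3 (−1.27 ± 0.16), the protein kinase A subunit gene PRKAR2B (−1.21 ± 0.16), the transcription factor gene KLF15 (−1.20 ± 0.26) and TAS1R3 (−1.18 ± 0.19).

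Replication and histone genes were again among those that fell. Of 36 G1/S and DNA replication genes, 7 fell and 0 rose (10 fell adjusted over the list alone), with PCNA at −0.52 ± 0.07, the thymidine kinase TK1 at −0.47 ± 0.11 and UHRF1, which maintains DNA methylation, at −0.43 ± 0.10. The list lay below other genes (camera adjusted p = 1.31e-15), a call lost at adjusted p = 0.0816 with an estimated correlation. It was kept when the libraries were also rescaled by trimmed means (camera adjusted p = 0.0283 with an estimated correlation). Of 26 clustered histone genes, 5 fell and 0 rose (14 fell adjusted over the list alone), among them HIST1H2BK (−1.05 ± 0.17), HIST1H2BD (−0.96 ± 0.14) and HIST1H2BC (−0.76 ± 0.17), and this list lay below other genes (camera adjusted p = 1.09e-14, and adjusted p = 0.028 with an estimated correlation), a call lost at adjusted p = 0.066 with the block and an estimated correlation. Of 35 mitosis and G2/M genes 0 passed. That list lay below other genes (camera adjusted p = 0.0389, lost at adjusted p = 0.735 with an estimated correlation), although its own median was 0.01 and its mean 0.00. WDR12, a ribosome biogenesis factor, rose by 0.44 ± 0.10 among 30 MYC and ribosome biogenesis genes (camera adjusted p = 0.561), and MYC was at −0.32 ± 0.11.

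**Figure D1:**
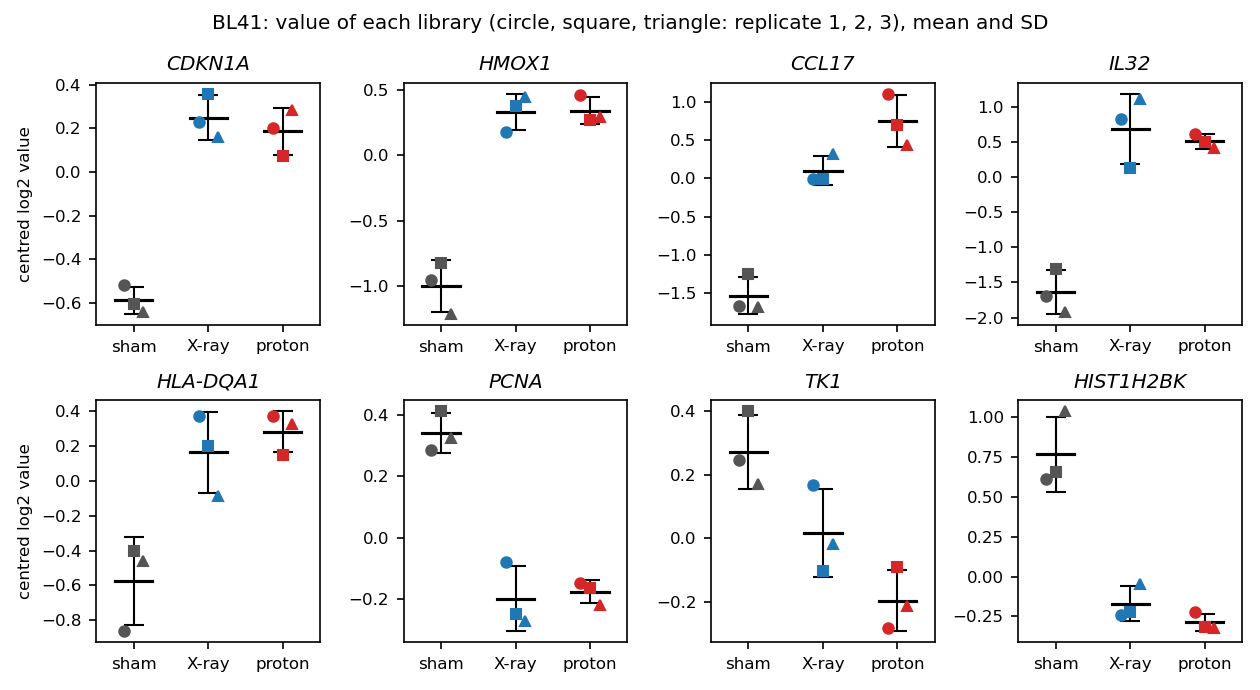
Centred log2 expression of 8 genes in the 9 BL41 libraries, with circles, squares and triangles for replicates 1, 2 and 3 and bars for the group mean and SD. CDKN1A, HMOX1, CCL17, IL32 and HLA-DQA1 lay higher in each irradiated group than in sham, and PCNA, TK1 and HIST1H2BK lower; TK1 passed the limma threshold after protons alone, and both radiation types lost every call with the replicate block.

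Of 23 NF-kB targets, 7 rose and 0 fell after protons (7 and 0 adjusted over the list alone), including CCL3, EBI3 and CCL4. The list did not pass (camera adjusted p = 0.102). STAT2 and IRF7 rose by 0.46 ± 0.11 and 0.43 ± 0.09 and were among the 4 risers of 29 interferon-stimulated genes (8 adjusted over the list alone; camera adjusted p = 0.102). Of 26 antigen presentation genes, 4 rose and 0 fell (10 and 0 adjusted over the list alone), with the uncertain values of HLA-DQA1 at 0.86 ± 0.15, HLA-DQB1 at 0.82 ± 0.14 and HLA-DRB1 at 0.81 ± 0.14. Of 20 NRF2 and antioxidant genes, 4 rose and 0 fell (6 and 0 adjusted over the list alone), among them HMOX1 and both subunits of the glutathione-synthesis enzyme, GCLM (0.40 ± 0.10) and GCLC (0.36 ± 0.07). The antigen presentation and NRF2 lists lay above other genes (camera adjusted p = 0.0389 and 0.0235), calls lost at adjusted p = 0.383 for each with an estimated correlation. With trimmed means 5 NF-kB, 3 antigen presentation, 1 NRF2 and 0 interferon-stimulated genes rose. Of 34 B-cell and germinal-centre genes, 3 rose and 2 fell (7 and 6 adjusted over the list alone), with the IgE receptor FCER2 at 0.86 ± 0.19, CCR7 at 0.74 ± 0.15 and the surrogate light chain VPREB1 at −0.83 ± 0.18. Of 10 plasma-cell genes TNFRSF13B rose (0.46 ± 0.10) and IGJ (−0.62 ± 0.11) and MZB1 (−0.35 ± 0.07) fell (camera adjusted p = 0.211).

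Single members of other lists passed after protons. CDKN1A was the 1 riser among 30 p53 targets (camera adjusted p = 0.102), and BBC3 was at −0.54 ± 0.18 (limma adjusted p = 0.0883), PMAIP1 at −0.14 and MDM2 at −0.06. The initiator caspase genes CASP8 (0.36 ± 0.09) and CASP9 (0.28 ± 0.07) rose among 28 apoptosis regulators (4 adjusted over the list alone; camera adjusted p = 0.996). RAD50 (0.45 ± 0.09), MDC1 (0.42 ± 0.10) and CHEK2 (0.34 ± 0.09) were 3 of the 4 risers among 39 DNA repair genes (camera adjusted p = 0.846). Of 38 oxidative phosphorylation genes 3 rose, among them SDHC at 0.40 ± 0.06 and NDUFA9 at 0.39 ± 0.10 (camera adjusted p = 0.223), and the sterol enzyme NSDHL rose (0.32 ± 0.07) among 23 sterol synthesis genes (camera adjusted p = 0.925). SLC2A3 rose (0.49 ± 0.12) among 30 glycolysis genes (0 adjusted over the list alone), and 0 of 25 stress-response genes passed (ATF4 at −0.44 ± 0.11, limma adjusted p = 0.051; HSP90B1 at 0.53 ± 0.16). The glycolysis, stress-response and B-cell lists lay below other genes (camera adjusted p = 0.0389, 0.0389 and 0.041) although their medians were −0.00, 0.03 and 0.04 and their means −0.01, 0.04 and −0.00. These calls were lost at adjusted p = 0.741, adjusted p = 0.383 and adjusted p = 0.502 with an estimated correlation, and at 0.15, 0.0686 and 0.0883 with libraries rescaled by trimmed means. Relative to all genes the glycolysis list was at −0.43, −0.233 and 0.266 in numbers 1 to 3. Of the markers of other cell types, the kinase gene LCK fell (−0.59 ± 0.13) among 5 T-cell and NK-cell markers (camera adjusted p = 0.102), CD163 was at 0.58 ± 0.15 (limma adjusted p = 0.0533) and 0 of 4 stromal, epithelial and erythroid markers passed (camera adjusted p = 0.846).

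After protons 891 genes were higher and 136 lower (limma, 1027 of 15069; 4278 at an unadjusted p under 0.05; 86.8% of calls higher). With the replicate block limma called 0 genes (lowest adjusted p = 0.0895, 2829 at an unadjusted p under 0.05). All 1027 had an unadjusted blocked p under 0.05 and the same sign in all 3 numbers. They too were picked from the same libraries, so this is no separate support. With the block and p adjusted over the list alone, 6 G1/S and 8 histone genes fell, 7 NF-kB, 4 antigen presentation, 3 NRF2 and 0 interferon-stimulated genes rose, and 3 B-cell genes rose and 2 fell. The 50 named genes past the threshold had blocked adjusted p between 0.122 and 0.181 in limma. The median fold change of all genes was 0.12 and moved to 0.01 with libraries rescaled by trimmed means, which gave 162 higher and 184 lower genes (46.8% higher), and quantile normalization gave 240 and 293 (45% higher). The count was 0, 3 and 10 without proton libraries 3, 1 and 2, 298, 460 and 568 without sham 3, 2 and 1, and 337, 684 and 710 without X-ray libraries 1, 2 and 3.

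The direct comparison of protons with X-rays at the same physical dose asked whether the beams differed in BL41. Among genes with an official symbol, those with the smallest p were SPECC1L, a cytoskeletal scaffold (0.98 ± 0.15), the fatty acid oxidation enzyme ECI1 (0.50 ± 0.08), the tumour antigen PRAME (−0.70 ± 0.11) and the matrix protein CHAD (−0.45 ± 0.07), none of them past the threshold (limma adjusted p = 0.339 for each). CDKN1A was at −0.06 ± 0.09 and MDM2 at 0.24 ± 0.16. All 30 MYC and ribosome biogenesis genes had values above 0 after protons relative to X-rays (median 0.25), 32 of 35 mitosis and G2/M genes had values below 0 (median −0.17) and 29 of 36 G1/S genes had values above 0 (median 0.09). These lists differed from other genes (camera adjusted p = 3.4e-08, 6.22e-07 and 0.0169), and each call was lost at adjusted p = 0.703 with an estimated correlation. Limma called 0 genes (1779 at an unadjusted p under 0.05, 790 with the replicate block), 1 with quantile normalization and 1 without proton library 1, and 2 NRF2 genes passed adjusted over the list alone (0 with the block).

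Both BL41 responses were measured against the same sham libraries. Among called genes, 384 were higher after both beams (43 for independent lists) and 46 lower after both (0.704 for independent lists), 376 were called after X-rays alone, 597 after protons alone, and 0 in opposite directions. Shared sham libraries favour calls in the same direction in both comparisons, so the numbers for independent lists are no baseline for this overlap. Across all 15069 genes, which are not independent replicates, the fold changes correlated with Pearson's r = 0.642 and Spearman's rho = 0.612. Simulated unchanged groups sharing their controls gave a mean r of 0.497 (highest 0.536) and 0 genes called in both. Unchanged groups give few calls at all, so that 0 is no measure for the shared calls. Omitting the 3 libraries of number 2 gave r = 0.529, within the range simulated for that design (mean 0.499, highest 0.538). Omitting X-ray library 2 gave 0.525 (simulated mean 0.459, highest 0.499). The covariance was 0.0448 against a simulated 0.0179, a difference of 0.0269. With 3 sham libraries the controls cannot be split into parts of 2, and part of the excess may come from the shared controls.

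**Figure D2:**
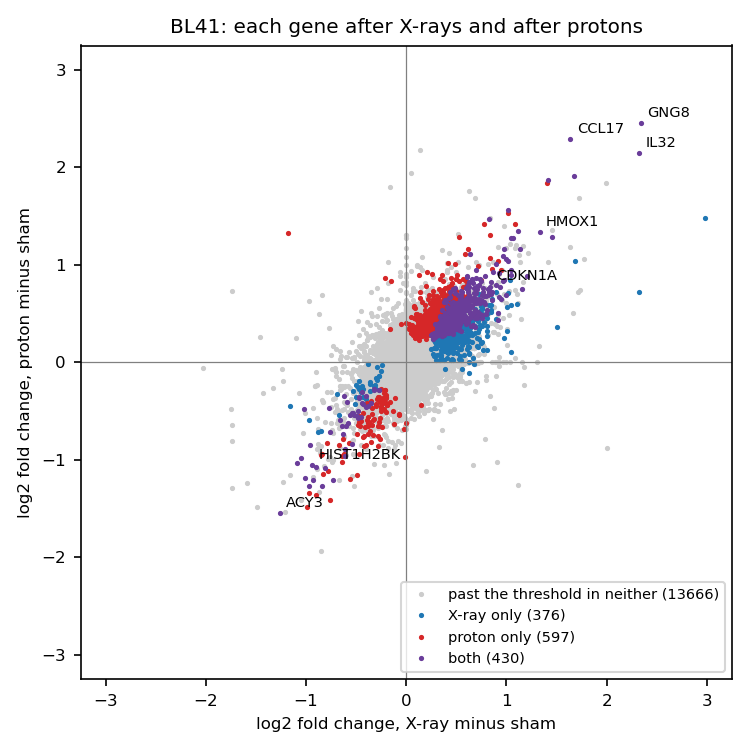
Log2 fold change after X-rays (horizontal) against that after protons (vertical) for the 15069 BL41 genes, coloured by which limma comparison called them. The genes called after both beams lie in the upper right (384) and lower left (46), and 0 lie in the other quadrants.

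In J3D the X-ray comparison gave no gene past the threshold. The histone gene Hist1h2ag had the value −0.71 ± 0.12 (n = 3 libraries per group, limma adjusted p = 0.441) and Hist1h2bh −0.65 ± 0.21, both uncertain because of near-identical copies. The p53 target Plk2, a polo-like kinase, was at 0.44 ± 0.11, Ccng1 at 0.29 ± 0.14, Cdkn1a at 0.17 ± 0.19, Mdm2 at −0.10 ± 0.08, Bbc3 at −0.46 ± 0.39 and Myc at 0.21 ± 0.19. All 22 sterol synthesis genes had values below 0, as did 26 of 29 glycolysis genes, 20 of 26 stress-response genes, 28 of 35 mitosis and G2/M genes and 12 of 17 histone genes. The sterol list included Lss (−0.58 ± 0.18) and Hsd17b7 (−0.27 ± 0.10), the glycolysis list Pfkl (−0.70 ± 0.17) and Eno1 (−0.41 ± 0.11), and the stress-response list Slc7a11 (−0.69 ± 0.18) and Ppp1r15a (−0.42 ± 0.11). Adjusted over the list alone, 7 stress-response genes, 2 glycolysis genes and 1 histone gene fell; with the replicate block 0 stress-response and 0 glycolysis genes did. Camera placed the sterol (adjusted p = 1.41e-09), glycolysis (6.11e-09), stress-response (2.33e-08), mitosis (0.0048) and histone (0.0054) lists below other genes, and the calls were lost with an estimated correlation, at adjusted p = 0.634 for mitosis and adjusted p = 0.363 for the others. Relative to all genes, the stress-response and histone lists lay above 0 in number 1 (0.025 and 0.0371).

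The other 15 lists did not pass in J3D after X-rays, with camera adjusted p from 0.0557 (apoptosis regulators) to 0.948. With trimmed means the apoptosis list passed upward (camera adjusted p = 0.0484), as it did with quantile normalization (0.0491), where the G1/S list also passed upward (0.00374). With an estimated correlation these calls were lost at camera adjusted p = 0.385, 0.449 and 0.736. Values in these lists included Herc6 at 0.25 ± 0.08 and Ifi35 at 0.36 ± 0.12 among 20 interferon-stimulated genes, Cd80 at 0.28 ± 0.09 among 13 antigen presentation genes, and Hba-a1 at 0.43 ± 0.31 and Hbb-b1 at 0.30 ± 0.17 among 6 stromal, epithelial and erythroid markers. Limma called 0 of 12264 genes (765 at an unadjusted p under 0.05, 413 with the replicate block). The libraries of number 1, which had the widest spread, entered this and the next comparisons, and without all 3 of them limma also called 0 genes after X-rays.

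After protons, no J3D gene passed either. Hist1h2ag was at −0.84 ± 0.12 (n = 3 libraries per group, limma adjusted p = 0.206), and the values of Plk2 (0.48 ± 0.11) and Ccng1 (0.48 ± 0.14) lay above 0 in all 3 numbers. Cdkn1a was at −0.35 ± 0.19, Mdm2 at 0.14 ± 0.08, Bbc3 at −1.01 ± 0.39 and Myc at 0.57 ± 0.19. Of 36 G1/S and DNA replication genes, 33 had values above 0, among them the origin-recognition gene Orc1 (0.67 ± 0.20) and the transcription factor gene E2f1 (0.33 ± 0.10), and so had 29 of 30 MYC and ribosome biogenesis genes, with Twistnb at 0.43 ± 0.14. Values below 0 were found for 26 of 29 glycolysis genes (Eno2 at −0.80 ± 0.28, Slc2a3 at −0.79 ± 0.28), 20 of 22 sterol synthesis genes (Mvd at −0.67 ± 0.19, Srebf2 at −0.59 ± 0.20), 18 of 26 stress-response genes (Trib3 at −1.47 ± 0.47, Cebpb at −1.02 ± 0.34) and 14 of 17 histone genes. Camera placed the G1/S (adjusted p = 1.54e-05) and MYC (0.00112) lists above other genes and the glycolysis (4.34e-07), sterol (1.71e-05), histone (0.000276) and stress-response (0.00783) lists below them, and all 6 calls were lost at adjusted p = 0.661 with an estimated correlation. The MYC list owed most of its value to the libraries of number 1, being at 0.554, 0.0878 and 0.0492 relative to all genes in numbers 1 to 3.

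The other 14 lists did not pass after protons in J3D, with camera adjusted p from 0.0709 (interferon-stimulated genes, with Stat2 at −0.80 ± 0.25) to 0.919. The interferon list passed downward with trimmed means (camera adjusted p = 0.0499) and quantile normalization (0.0306). These calls were lost at adjusted p = 0.669 and adjusted p = 0.707 with an estimated correlation. The antioxidant genes Gpx1 and Prdx1 were at 0.45 ± 0.13 and 0.31 ± 0.10, and the endothelial marker Kdr was at −0.45 ± 0.18. Adjusted over the list alone, Plk2 rose and Hist1h2ag fell, and with the replicate block Hist1h2ag alone passed. Limma called 0 of 12264 genes (2425 at an unadjusted p under 0.05, 1134 with the replicate block). It called 1 gene without proton library 1 and 1 without proton library 3. Without proton libraries 1, 2 and 3, 843, 1769 and 2453 genes had an unadjusted p under 0.05.

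**Figure D3:**
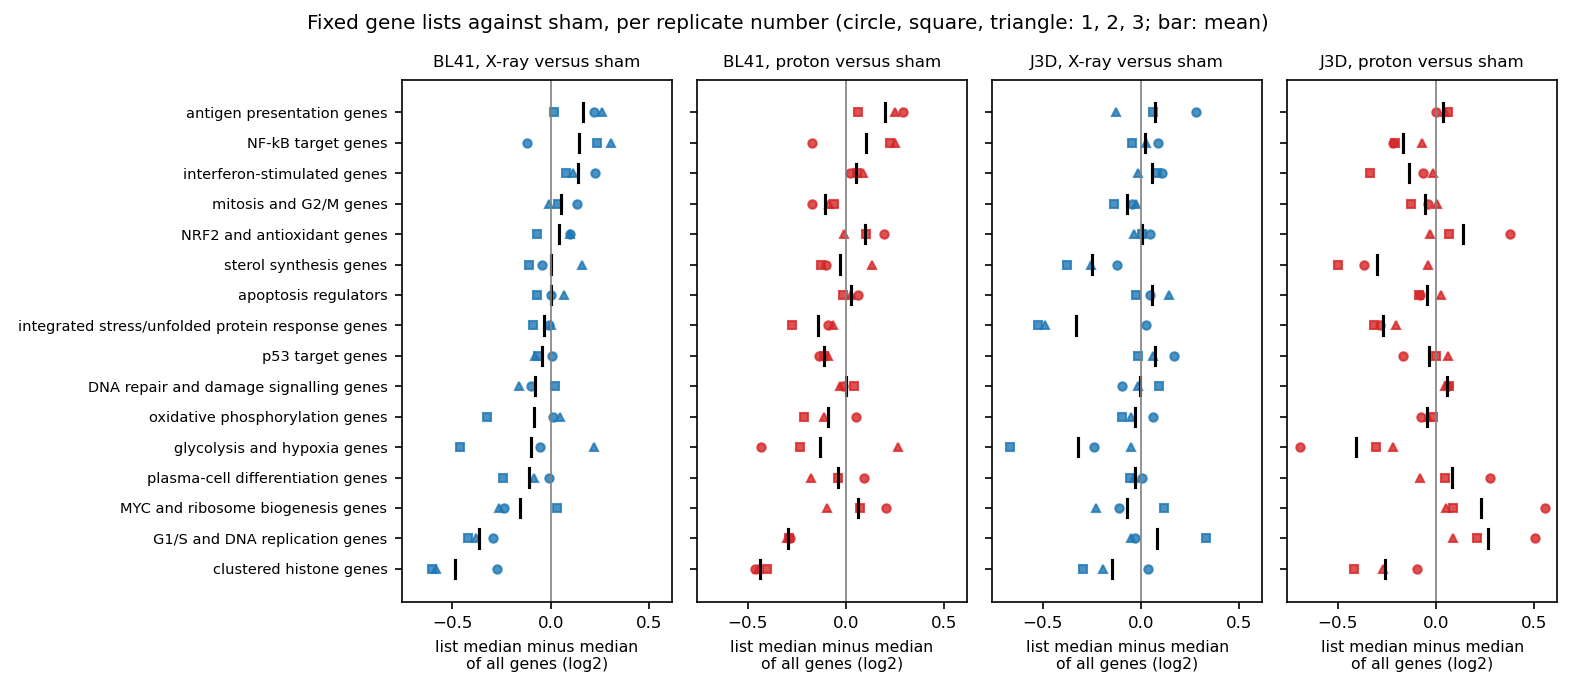
Median log2 fold change of 16 gene lists relative to the median of all genes, for each replicate number (points) and their mean (bars), in 4 panels for X-rays and protons in BL41 and J3D. The G1/S list lay at a mean of −0.292 in BL41 and 0.266 in J3D after protons, and the camera calls of both were lost with an estimated correlation.

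Protons against X-rays in J3D gave, among genes with an official symbol, the smallest p for Ctla2b (−0.71 ± 0.11, limma adjusted p = 0.16), the cilium gene Rsph9 (−0.55 ± 0.09, 0.217), C1qtnf7 (−0.62 ± 0.12, 0.392) and Fam129b (0.59 ± 0.12, 0.392). Cdkn1a was at −0.51 ± 0.19 and Mdm2 at 0.24 ± 0.08. All 30 MYC and ribosome biogenesis genes and 32 of 36 G1/S genes had values above 0, and 17 of 20 interferon-stimulated genes had values below 0. These lists differed from other genes (camera adjusted p = 4.06e-07, 0.000323 and 0.000323), and all 3 calls were lost at adjusted p = 0.74 with an estimated correlation. Relative to all genes in numbers 1 to 3, the MYC list was at 0.648, −0.0379 and 0.22, the G1/S list at 0.536, −0.116 and 0.137 and the interferon list at −0.144, −0.419 and 0.0291, so that each had 1 number of opposite sign. Limma called 0 genes (lowest adjusted p = 0.147; 1456 at an unadjusted p under 0.05, 608 with the replicate block), but 1 without sham library 3 and 1 without X-ray library 3.

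The J3D fold changes after X-rays and protons correlated across 12264 genes with r = 0.501 and rho = 0.469. Simulated unchanged groups sharing their controls gave a mean r of 0.513 (highest 0.723). The covariance was 0.0292 against a simulated 0.0235, a difference of 0.00571. Without X-ray library 2, r was 0.164 (simulated mean 0.45, highest 0.59). Omitting the 3 libraries of number 1 gave r = 0.628, above the highest simulated value of 0.62 (mean 0.492). The draws used 1 noise level per gene, estimated with the wide-spread number 1 included, so they cannot judge so small an excess.

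Between the lines, 8296 genes were matched by symbol, and 0 were called by limma in both because none was called in J3D. At an unadjusted p under 0.05, 52 genes were higher after X-rays in both lines where 37.4 were expected (two-sided Fisher's exact test, p = 0.00883, adjusted p = 0.0706 over 8 tests), and 6 were lower where 7.38 were expected. After protons 236 were higher in both (261 expected) and 39 lower in both (28.5 expected), each with an adjusted p of 0.142 in Fisher's exact test. The 8 tests included those at the adjusted threshold, whose outcome was fixed because J3D had no calls. Counting them raises the adjusted p of the others. Fisher's test also takes genes as independent, which genes of the same libraries are not, so its p-values may be too small. The fold changes of the lines correlated across genes with r = 0.0192 after X-rays and 0.0884 after protons.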

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

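The 3 tests of explanations in this part were chosen only after the result was seen. After protons, 2 gene lists lay on opposite sides of the median of all genes in every replicate number of the lines. For G1/S and DNA replication genes, the mean over the 3 numbers of the list median relative to all genes was −0.292 in BL41 and 0.266 in J3D. For interferon-stimulated genes it was 0.0538 in BL41 and −0.138 in J3D, and that difference was not tested. Of the 32 pairs of list and contrast looked at, 3.12% would do so by chance, which is 1 pair, and 2 were found.

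The G1/S difference between the lines after protons was 0.558 (J3D minus BL41), with values of −0.286, −0.29 and −0.301 in numbers 1 to 3 of BL41 and of 0.502, 0.211 and 0.0853 in J3D. The J3D mean over numbers 2 and 3 was 0.148 (SE 0.0627), and the sides were opposite in 6 of 6 pairs of same-numbered libraries. Because the list was picked for lying on opposite sides in every number, neither value can decide whether the wide-spread J3D libraries of number 1 or a library-wide shift account for the difference. The two-sided exact permutation p over the 6 values was 0.1, the smallest that 3 against 3 can give, so this test decides nothing either. A different cell-cycle response of the lines to protons may account for the difference, as may any other difference between a human and a mouse line, and neither was tested.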

How the results depend on the processing

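Counts of calls moved with most settings. With the replicate block, limma called 0 genes higher and 0 lower in both BL41 comparisons with sham, with 4 residual degrees of freedom in place of 6. It changed no count over all genes in J3D, ended the J3D calls adjusted over the list alone of stress-response and glycolysis genes after X-rays and of Plk2 after protons, and among camera calls it added NF-kB targets and mitosis after X-rays in BL41. The same 0 calls came from the block with trimmed-mean rescaling and from the 6 libraries of the compared groups alone, and the block without trend and robust gave 0 and 0 after X-rays and 1 higher and 2 lower after protons. BL41 genes higher and lower numbered 217 and 117 after X-rays and 162 and 184 after protons with libraries rescaled by trimmed means, 74 and 55 and then 240 and 293 with quantile normalization, 3 and 0 and then 1 and 0 omitting the 3 libraries of number 2, and 28 and 6 and then 32 and 19 with an absolute log2 fold change of at least 1. With trimmed means 291 of the 806 and 290 of the 1027 calls stayed. Leaving out 1 library gave 0 to 739 higher and 0 to 69 lower genes after X-rays (0 without X-ray library 1) and 0 to 630 higher and 0 to 100 lower after protons (0 without proton library 3), where a group of 2 is assumed to vary like the others. For protons against X-rays in BL41 quantile normalization gave 1 gene and leaving out 1 library 0 to 1 (1 without proton library 1). In J3D leaving out 1 library gave 0 to 1 genes higher after protons (1 without proton library 1 or 3) and 0 to 1 for protons against X-rays (1 without sham 3 or X-ray 3).

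The BL41 correlation of the X-ray and proton fold changes was 0.809 over genes past the threshold in either contrast, which selects for shared direction. It was 0.529 omitting the 3 libraries of number 2 and 0.525 (without X-ray library 2) to 0.702 on leaving out 1 library. Simulated unchanged groups reached 0.538 omitting number 2 and 0.499 without X-ray library 2. In J3D the correlation was 0.164 (without X-ray library 2) to 0.693 on leaving out 1 library. The simulated J3D mean without X-ray library 2 was 0.45 (highest 0.59). Omitting number 1 in J3D gave 0.628, above the simulated highest of 0.62, an excess too small for draws whose noise was estimated with number 1 included. Of the gene list calls of camera, an estimated correlation left 2 of 5 after X-rays and 1 of 8 after protons in BL41, and 0 for protons against X-rays in BL41 and for all J3D contrasts. With the block as well, the G1/S and histone calls stayed after X-rays (camera adjusted p = 0.0388 for each) and none after protons (0.0928 and 0.066). Fry called 8 lists after X-rays and 8 after protons in BL41, and 0 for protons against X-rays in BL41 and for all J3D contrasts. It tests a list against no change rather than against other genes, and the median of all BL41 genes lay above 0. The fry lists were therefore partly others. After X-rays fry left out MYC (fry adjusted p = 0.499) and called apoptosis regulators (0.00293, camera adjusted p = 0.9). After protons it left out the glycolysis and B-cell lists (fry adjusted p = 0.971 for each). Omitting the 3 libraries of number 2 left 5 lists after protons in BL41. The overlap between the lines at an unadjusted p under 0.05, summed over contrasts and directions so that a gene can count more than once, was 333, about the sum of the expected numbers. Named genes gave 3006 pairs of result and setting, of which 1926 kept direction and side of the threshold, 1070 lost the threshold, 6 gained it and 4 turned in direction. That total includes genes that were not past the threshold and had no call to lose, such as all those of J3D. For the named BL41 genes past it, 259 of 792 pairs kept the call after X-rays and 533 lost it. After protons 363 of 900 kept the call and 537 lost it. BL41 X-ray versus sham PMAIP1 log2 fold change turned to 0.0398 and BL41 proton versus X-ray CDKN1A log2 fold change to 0.0495 omitting the 3 libraries of number 2. BL41 proton versus sham MDM2 log2 fold change ranged from −0.136 to 0.0833 (without sham 3), and J3D X-ray versus sham Cdkn1a log2 fold change from −0.00614 (without X-ray library 1) to 0.32, on leaving out 1 library. For the other moves the cause was not tested. Another pseudocount, other filters and DESeq2 were not run, because the values are centred logarithms without counts or levels, and depth as a limit could not be examined.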

Other observations

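All tests of explanations and pathway terms in this part were chosen only after the result was seen, while the counts over other splits of the samples were planned. The tables carry a pathway column, whose terms of 10 to 200 genes were tested with camera (58 terms in BL41, 112 in J3D). Cytoplasmic ribosomal protein genes lay below the median of all genes for 80 of 87 members after each beam in BL41 (camera adjusted p = 1.34e-08 after X-rays and 6.26e-16 after protons), and for 80 and 79 of 89 members in J3D (6.28e-05 and 2.54e-09). After X-rays the medians relative to all genes in numbers 1 to 3 were −0.0619, −0.538 and 0.0874 in BL41 and −0.00493, −0.314 and −0.00214 in J3D, so that number 2 carried the value. After protons they were −0.21, −0.386 and −0.161 in BL41 and −0.411, −0.134 and −0.165 in J3D. None of these calls held with an estimated correlation (adjusted p = 0.984, 0.832, 0.988 and 0.999), and many ribosomal protein genes share reads with pseudogenes.

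Redox and immune terms lay above other genes in BL41, and with the replicate block 0 of the genes counted here were called. In glutathione metabolism 4 of 13 genes rose after each beam (camera adjusted p = 0.0365 after X-rays and 0.0179 after protons; adjusted p = 0.508 and 0.408 with an estimated correlation). In the NRF2 pathway 10 of 70 genes rose after X-rays and 12 after protons (camera adjusted p = 0.0102 and 0.0117; 0.956 and 0.786 with an estimated correlation). After protons, 8 of 54 proteasome genes and 11 of 71 Toll-like receptor pathway genes rose (camera adjusted p = 0.0117 and 0.0144; 0.98 and 0.925 with an estimated correlation), the proteasome term being at 0.337, −0.0298 and 0.0844 relative to all genes in numbers 1 to 3. In J3D all 14 cholesterol biosynthesis genes lay below the median after each beam (camera adjusted p = 7.86e-08 and 8.44e-05; 0.988 and 0.999 with an estimated correlation).

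Most BL41 genes called against sham were higher after irradiation, 90.3% after X-rays and 86.8% after protons. Without sham library 2, which had the lowest mean, 83.7% of calls after X-rays and 78.3% after protons were higher. Through the centring a shift of that library also moves the other libraries of number 2, so this cannot exclude it. Omitting all 3 libraries of number 2 gave 3 calls after X-rays and 1 after protons. At an unadjusted p under 0.05 in limma, 2038 genes were then higher and 855 lower after X-rays, and 2679 and 705 after protons. At that threshold the excess thus did not rest on number 2 alone. With libraries rescaled by trimmed means 65% and 46.8% of calls were higher, and with quantile normalization 57.4% and 45%. Both rescalings centre every library and so pull this share towards the middle whatever its source, and a shift of whole libraries and a true excess cannot be told apart by them. A wider rise of transcripts after irradiation was not tested.

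The J3D table holds few B-cell genes. Of 37 B-cell and germinal-centre genes only Btk, Cd22 and Lyn (8.11%) have values there, against 34 (91.9%) in BL41, and 25 of 37 erythroid and megakaryocyte genes have values in J3D against 8 in BL41, 18 of the 37 having been looked up when the list was written. All of these 18 have values in J3D, so 25 against 8 is no fair comparison of the lines. Matched by description, 1 of 34 B-cell genes (2.94%) but 198 of 401 genes of lists not about cell type (49.4%) were found (two-sided Fisher's exact p = 1.94e-08). This match missed B-cell genes that the symbols had found, so it cannot decide whether gene names differ. Of the 19 erythroid and megakaryocyte genes not looked up before, 7 (36.8%) have values in J3D and 4 (21.1%) in BL41; the J3D share was above that of B-cell genes (two-sided Fisher's exact p = 0.0223), but the low B-cell share had prompted the test, which therefore decides nothing. In a mixture made up largely of B cells, most B-cell genes would have values. The 8.11% lie below that, but this share had prompted the question and is no separate test of it. Gene names or the selection of genes may also have removed B-cell genes. Whether the line itself or a small share of B cells among other cells accounts for the missing genes stays open. By symbol, all 36 G1/S, 35 mitosis and 39 DNA repair genes have values in J3D, which argues against differing names for those genes. Other lists were found in part, such as 16 of 28 NF-kB targets and 20 of 33 interferon-stimulated genes. Names that differ for B-cell genes and the selection of the tables' genes, which is not given, stay open too.

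The 6 libraries of each pair of groups can be split in 10 ways, too few for a share under 0.05. In BL41, the real X-ray split called 806 genes and the highest other 0 (1 split as large, the real one), and the real proton split 1027 and the highest other 1 (1 as large). For protons against X-rays in BL41 the real split called 0 and the highest other 3 (10 as large). In J3D the real split called 0 genes in each contrast (10 as large), and the highest other 1 after X-rays, 0 after protons and 1 for protons against X-rays. At an unadjusted p under 0.05 the real and highest other counts were 3555 and 1893, 4278 and 978, and 1779 and 1869 in BL41, and 765 and 1802, 2425 and 644, and 1456 and 2800 in J3D.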
